A study of Arabidopsis thaliana with 20 samples.

How the data were processed

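RNA was sequenced from shoots in 20 libraries of 7 groups, in 3 label batches: DM1-DM2d (n = 3) with Col-0 12 DAS (n = 2), DM6-DM7 (n = 3) with Col-0 14 DAS (n = 3), and DM1-DM2d adr1s, DM6-DM7 adr1s and Col-0 adr1s (n = 3 each). The deposited file holds raw counts per gene, in the unit counts, for 32833 genes, with no normalization. Per the labels the libraries were strand-specific and read as 150 bp pairs on an Illumina NovaSeq. How RNA was selected before library preparation is not given. The processing notes name fastp 0.23.2, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 1.34.0 and the genome build TAIR10. The options used for counting are not stated in the sources. Between 64.9% and 78% of counts below 20 were even numbers, depending on the library, so both mates were counted for most fragments. Chromatin accessibility data named in the same notes were not analysed here. Every value was a whole number, no library was a duplicate of another, and gene identifiers matched the annotation (TAIR10.1) for 32548 genes (99.1%). The other 285 were plastid (133) and mitochondrial (152) genes.

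Groups were taken from the labels. The libraries held 48360933 to 127276992 counts, and the floor for a gene with a count of 0 was set at 3 counts per library. With both mates counted for most fragments, 3 fragments would be up to 2 times this floor, and bounds on folds up to 2 times smaller. Such limits cover counting error only, since reads were not tagged by molecule. Counts per 1000000 (CPM) used the library totals scaled by trimmed mean of M values (TMM) factors, which ran from 0.723 to 1.25.

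All 20 libraries entered 1 fit with a term per group in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 23349 genes. Dispersions and the quasi-likelihood fit were robust, and p values were adjusted by Benjamini-Hochberg within each of 11 contrasts, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. The contrasts were each line against the Col-0 group of its batch (4), the effect of each pair minus its effect in adr1s (2), the DM1-DM2d effect minus the DM6-DM7 effect, DM1-DM2d adr1s against DM6-DM7 adr1s, and 3 between Col-0 groups of different batches. Each group lies in 1 label batch, so batch was not a term.

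Sets of genes were 28 lists of 450 genes, of which 442 were tested: helper NLR and EDS1 node, DM target loci, salicylic acid synthesis and regulation, systemic acquired resistance and N-hydroxypipecolic acid, camalexin and indole metabolism, pattern-triggered immunity, NLR receptors, jasmonate, abscisic acid and cold response, ER protein folding, glutathione and redox, senescence, light harvesting, photosystem subunits, Calvin cycle, chlorophyll synthesis, cell cycle, auxin, cell wall expansion, brassinosteroid and gibberellin, growth transcription factors, aliphatic glucosinolates, anthocyanins, iron homeostasis, circadian clock, stomatal lineage, root markers, and meristem and floral markers. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 224 pairs of list and contrast (8 contrasts). Of these 127 passed, and 1 passed with an estimated correlation: jasmonate in DM1-DM2d adr1s against DM6-DM7 adr1s. The test fry, which asks whether the genes of a list move on balance in 1 direction, was run beside it.

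Named genes were taken by a rule: the ADR1 genes and DM target loci, the 5 highest and 5 lowest log2 fold changes among genes past the threshold with a mean of at least 2 CPM and, for contrasts of 2 groups, no overlap between their libraries, and per list up to 3 called members with the lowest adjusted p in the majority direction and 1 in the other. Where a list had no called member, the one with the highest mean CPM was open to naming. PR1 in DM6-DM7 against Col-0 14 DAS lies outside this rule and was named after its values were seen. Of the genes the rule allows, those whose calls held under the alternatives were preferred for naming. The result for 1 gene that the rule allows is not reported here. Where a group had no counts for a gene, the fold change was given as a bound against 3 counts over the group. Positions are those of the annotation.

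The pipeline was tested on simulated data with 100 genes changed at 2-fold and 100 at 4-fold. At 2-fold it recovered 54% (DM1-DM2d), 59% (DM6-DM7), 59% (DM1-DM2d adr1s) and 58% (DM6-DM7 adr1s), and 46% in the difference of effects for DM6-DM7. At 4-fold it recovered 79%, 79%, 80%, 82% and 69%. False calls were, in the same order, 3.62%, 3.5%, 9.15%, 2.78% and 3.36% of calls, so those of DM1-DM2d adr1s lay above the nominal 5%. Overlaps between lines were set against independence and, where the control libraries were shared, against 20 simulations without effect.

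Alternatives were other scalings (RLE, upper quartile), no filter and a minimum of 50 counts, DESeq2 1.42.0, an adjusted p of 0.01, a fold threshold of 2, a fit of the libraries of each contrast alone, the replicate number as a block, and each replicate left out. Fits without plastid and mitochondrial genes and with counts halved were added after seeing the data. Other splits of the libraries into groups of the same sizes were fitted in the same way.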

Results

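RNA was sequenced from Arabidopsis thaliana shoots of 7 groups, 20 libraries in all, and counted over 32833 genes. DANGEROUS MIX (DM) genes are immune receptor loci and partner loci whose natural alleles cause autoimmunity when brought together in 1 plant. In the lines studied here a pair of such genes had been put into Col-0, the reference accession: DM1 with DM2d, both of the TIR type of nucleotide-binding leucine-rich repeat receptor (NLR), and DM6 with DM7, an RPP7-type receptor with an RPW8/HR-type protein. The adr1s background lacked working ADR1, ADR1-L1 and ADR1-L2, the 3 helper NLR genes that act downstream of many receptors, after CRISPR editing. DM1-DM2d (n = 3) and its Col-0 control (n = 2) were 12 days after sowing (DAS), and DM6-DM7 (n = 3) and its Col-0 control (n = 3) were 14 DAS. The labels gave no separate age for DM1-DM2d adr1s, DM6-DM7 adr1s and Col-0 adr1s (n = 3 each). The libraries held between 48360933 and 127276992 counts. The range was 93549230 to 104370141 in DM1-DM2d, 86880565 to 89792404 in Col-0 12 DAS, 97800801 to 119100007 in DM6-DM7 and 105452598 to 127276992 in Col-0 14 DAS. It was 49723321 to 58867219 in DM1-DM2d adr1s, 50872700 to 56313562 in DM6-DM7 adr1s and 48360933 to 58724115 in Col-0 adr1s. For a gene with no counts in a library a floor of 3 counts is 0.024 to 0.062 counts per 1000000 (CPM) before TMM scaling. Such floors cover counting error only. Both mates were counted for most fragments, so a floor of 3 fragments would be up to 2 times as high. Each of the 3 label batches held its own control, so each line was set against the Col-0 group of its batch.

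All 3 edited genes still gave transcripts in the adr1s libraries. ADR1 (AT1G33560; TAIR10, chromosome 1, 12168768 to 12172119) stood at 10.1 ± 2.1 CPM (SD, n = 3) in Col-0 adr1s, against 21.4 ± 0.083 in Col-0 12 DAS (n = 2) and 18.3 ± 6.2 in Col-0 14 DAS (n = 3). It stood at 186 ± 4.7 CPM in DM1-DM2d, 83.4 ± 4.7 in DM6-DM7, 62.1 ± 4.9 in DM1-DM2d adr1s and 37.5 ± 6.4 in DM6-DM7 adr1s. ADR1-L1 (AT4G33300; chromosome 4, 16050456 to 16056526) stood at 536 ± 28 CPM in DM1-DM2d, 78.3 ± 13 in Col-0 12 DAS, 264 ± 8.2 in DM6-DM7 and 51.4 ± 11 in Col-0 14 DAS. In the knockout it was at 56.2 ± 3.4 CPM with DM1-DM2d, 113 ± 17 with DM6-DM7 and 30.8 ± 1.4 with neither. ADR1-L2 (AT5G04720; chromosome 5, 1360589 to 1363907) was at 196 ± 9 CPM in DM1-DM2d, 109 ± 2.8 in DM6-DM7, 44.1 ± 0.31 in Col-0 12 DAS and 42.9 ± 10 in Col-0 14 DAS. In the knockout it was at 26.3 ± 0.28 CPM with DM1-DM2d, 16.9 ± 2.6 with DM6-DM7 and 16.3 ± 4.1 with neither. Gene counts do not show whether a transcript carried the edit, so the knockout rests on the labels.

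**Figure D1:**
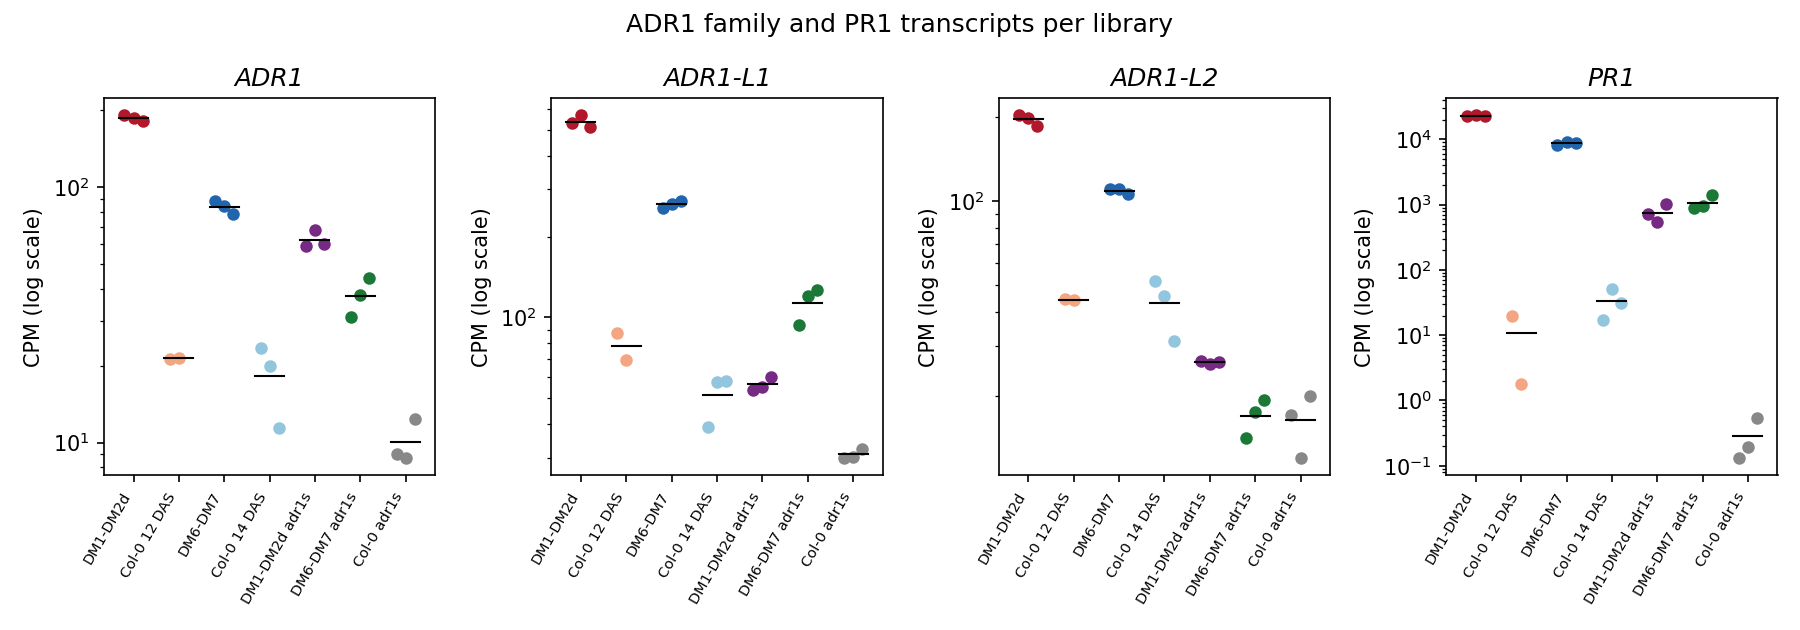
CPM (log axis) of ADR1, ADR1-L1, ADR1-L2 and PR1 in each of the 20 libraries, 1 point per library, with a line at the mean of each group. PR1 averaged 23000 CPM in DM1-DM2d and 0.286 CPM in Col-0 adr1s.

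The first comparison asked what the DM1-DM2d pair changed with the ADR1 genes intact, 3 libraries against 2 of Col-0 12 DAS. PR1 (AT2G14610; chromosome 2, 6241640 to 6242541), a pathogenesis-related protein gene induced by salicylic acid, rose from 10.8 ± 13 CPM to 23000 ± 360 CPM, a log2 change of 11.05 ± 1.05 (SE). The 2 Col-0 12 DAS libraries stood apart on immune genes. Replicates 1 and 2 had 19.9 and 1.78 CPM of PR1, 41.9 and 7.93 of ICS1, 37.1 and 12.5 of PAD4 and 7.64 and 0.159 of FMO1, and the cause was not tested. The PR1 change was 13.6 without replicate 1 and 10.09 without replicate 2. Higher were 19 of 20 genes of the salicylic acid list (1 lower), 13 of 18 NLR receptors (1 lower) and 9 of 12 senescence genes. Lower were 22 of 22 genes of photosystem subunits, 30 of 31 of the cell cycle (1 higher), 22 of 26 of auxin (1 higher) and 8 of 9 of the stomatal lineage (1 higher). These lists passed the gene set test camera at a preset correlation. None passed with an estimated one (adjusted p from 0.13 to 0.607). NPR3 (AT5G45110), a salicylic acid receptor gene, rose by 4.38 ± 0.16 (adjusted p = 1.72e-13), and LHCA6 (AT1G19150), of the antenna of photosystem I, fell by 5.8 on the log2 scale (SE 0.18, adjusted p = 2.58e-14). Of 23349 genes tested, 17045 differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 8555 higher and 8490 lower, and 11954 of them by at least 2-fold (5546 higher, 6408 lower). Of the called genes 50.2% were higher, but 41% with upper-quartile scaling (6974 higher, 10032 lower), so the balance depends on the scaling. Lower genes were also the majority without DM1-DM2d replicate 3 (8101 higher, 8293 lower), Col-0 12 DAS replicate 1 (7494 and 8067) or its replicate 2 (7278 and 8051).

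Each group of genes below is a list fixed before the data were examined, tested with camera at a preset correlation, and the value after ± is the standard error of a log2 change. The count adjusted over the list alone is given wherever it differed from the count over all genes. All 10 measured members of the helper NLR and EDS1 node rose (median 3.01, adjusted p = 2.06e-05, or 0.159 with an estimated correlation). ADR1 rose by 3.12 ± 0.25, ADR1-L1 by 2.77 ± 0.17, ADR1-L2 by 2.15 ± 0.2, SAG101 (AT5G14930), which pairs with EDS1, by 2.97 ± 0.19 and NRG1.2 (AT5G66910), of another helper NLR family, by 3.04 ± 0.21. Among the 18 DM target loci 12 rose and none fell (median 1.81, adjusted p = 0.00302, or 0.332 with an estimated correlation). The neighbouring TIR-type genes of the DM1 locus, AT5G41740 (chromosome 5, 16688626 to 16693119) and AT5G41750 (16693832 to 16699028), rose by 3.27 ± 0.24 and 4.91 ± 0.53, and AT3G44400 of the RPP1 cluster, where DM2 lies, by 3.48 ± 0.16. HR3 and HR4 (AT3G50480; chromosome 3, 18733021 to 18734420), relatives of DM7 that were not part of this pair, rose by 5.74 ± 0.63 and 4.7 ± 0.63. Another, HR2, had 3.22 ± 0.29 CPM in DM1-DM2d (SD, n = 3) and 2 counts over Col-0 12 DAS, too few for a fold. The counts do not separate transcripts of the introduced genes from those of their Col-0 relatives.

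In DM1-DM2d 19 of 20 genes of salicylic acid synthesis and regulation rose and 1 fell (median 5.09, adjusted p = 1.02e-05, or 0.272 with an estimated correlation). NPR4 (AT4G19660), the second such receptor named, rose by 2.27 ± 0.16 and the transcription factor gene WRKY54 (AT2G40750) by 6.52 ± 0.43, while NIMIN3, whose product binds NPR1, changed by -1.1 ± 0.13. In the systemic acquired resistance and N-hydroxypipecolic acid list 8 of 10 members rose (median 3.79, adjusted p = 0.049, or 0.585 with an estimated correlation), with PR5 (AT1G75040) at 3.62 ± 0.34 and the pipecolic acid synthesis gene SARD4 at 3.42 ± 0.37. The size of these changes rests on the control. Without Col-0 12 DAS replicate 1 the medians of the 2 lists were 6.03 and 6.28 and SARD4 stood at 4.35; without replicate 2 they were 4.66 and 3.13, and SARD4 at 2.76. Of 26 genes of pattern-triggered immunity 22 rose and 1 fell (median 2.05, adjusted p = 2.98e-05, or 0.159 with an estimated correlation), among them the receptor kinase genes BIR1 (AT5G48380) at 2.51 ± 0.12 and BKK1 at 2.36 ± 0.14. PEPR1, the receptor of Pep peptides, changed by -0.72 ± 0.21. Of 18 other NLR receptors 13 rose and 1 fell (median 0.72, adjusted p = 0.0471, or 0.607 with an estimated correlation), with ZAR1 at 1.42 ± 0.12 and RPP2A at -1.05 ± 0.08.

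Of 15 genes of ER protein folding 12 rose (median 1.32, adjusted p = 0.00877, or 0.475 with an estimated correlation), with BZIP28, an ER stress transcription factor gene, at 2.19 ± 0.09. Of 12 senescence genes 9 rose (median 2.66, adjusted p = 0.00415, or 0.159 with an estimated correlation): SGR1 (AT4G22920) and PAO, both of chlorophyll breakdown, rose by 4.4 ± 0.29 and 2.09 ± 0.12, and ORE1 (AT5G39610), a NAC transcription factor gene, by 3.3 ± 0.2. Without Col-0 12 DAS replicate 1 the senescence median was 3.3.

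All 19 light harvesting genes (median -5.25), all 22 genes of photosystem subunits (median -4.14) and all 17 Calvin cycle genes (median -3.92) fell in DM1-DM2d. So did 14 of 15 chlorophyll synthesis genes (median -3.6). The adjusted p values were 3.29e-17, 2.1e-28, 2.71e-24 and 2.4e-10, and with an estimated correlation the adjusted p was 0.134 for light harvesting and 0.13 for the other lists. LHCB5 changed by -5.24 ± 0.2, PSBR by -4.02 ± 0.13, SBPASE (AT3G55800), the sedoheptulose bisphosphatase gene, by -4.24 ± 0.12, HCEF1, a fructose bisphosphatase gene, by -4.64 ± 0.13 and CHLG, the chlorophyll synthase gene, by -3.31 ± 0.1. In the same libraries 10.9 ± 0.57% of counts lay on plastid-encoded genes (SD, n = 3), against 42 ± 0.28% in Col-0 12 DAS (n = 2), and 119 of 127 plastid-encoded genes were lower.

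Of 31 cell cycle genes 30 fell and 1 rose (median -2.77, adjusted p = 1.03e-07, or 0.356 with an estimated correlation), with the cyclin gene CYCD3;1 at -2.78 ± 0.16 and MCM7, of DNA replication, at -1.94 ± 0.12. Of 26 auxin genes 22 fell and 1 rose (adjusted p = 0.000339, or 0.347 with an estimated correlation), with a median of -4.05, or -3.59 with genes absent from 1 group set at their bound. IAA3 changed by -5.09 ± 0.29, the efflux carrier gene PIN3 by -3.47 ± 0.21 and SAUR9 by 4.11 ± 0.33. Of 17 genes of cell wall expansion 10 fell and 3 rose (median -2.89, adjusted p = 0.0275, or 0.462 with an estimated correlation), with the expansin gene EXPA5 (AT3G29030) at -8.03 ± 0.31 and XTH24 at 5.24 ± 0.42. Of 15 brassinosteroid and gibberellin genes 11 fell and 1 rose (median -1.88, adjusted p = 0.0449, or 0.301 with an estimated correlation), with GASA4 at -3.9 ± 0.12 and BZR1 at 1.43 ± 0.09. Of 13 growth transcription factors 11 fell and 2 rose (median -2.74, adjusted p = 0.015, or 0.237 with an estimated correlation), with ANT at -5.1 ± 0.38 and PIF4 at -4.3 ± 0.27. All 11 genes of aliphatic glucosinolates fell (median -3.02, adjusted p = 2.73e-08, or 0.143 with an estimated correlation), with MYB28 at -3.8 ± 0.19. Of 9 stomatal lineage genes 8 fell and 1 rose (median -4.91, adjusted p = 0.000181, or 0.169 with an estimated correlation), with SPCH (AT5G53210), which starts the lineage, at -6.36 ± 0.34 and TMM at -4.32 ± 0.22. SPCH stood at -7.02 without DM1-DM2d replicate 3.

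The remaining lists did not pass camera in DM1-DM2d. In camalexin and indole metabolism 8 of 16 genes rose and 4 fell (median 1.06, adjusted p = 0.312), with CYP82C2 at 11.9 ± 1.24 and GGP1 at -0.83 ± 0.1. CYP82C2 stood at 16.24 without Col-0 12 DAS replicate 1 and at 10.89 without replicate 2. Of 27 jasmonate genes 9 rose and 13 fell (median -0.46, adjusted p = 0.326): the synthesis genes AOS (AT5G42650) and AOC1 (AT3G25760) changed by -2.92 ± 0.1 and -6.84 ± 0.3, and CYP94C1, of jasmonate breakdown, by 3.57 ± 0.31. In glutathione and redox 9 of 12 rose and 2 fell (median 2.26, adjusted p = 0.051), with the peroxidase genes PRX34 at 6.89 ± 0.35 and PRX33 at -4.19 ± 0.43. In abscisic acid and cold response 6 of 14 fell and 2 rose (1 when adjusted over the list alone; median -2.17, adjusted p = 0.573), with RD29A at -5.46 ± 0.66. In anthocyanins 3 of 9 fell (2 when adjusted over the list alone; median -0.58, adjusted p = 0.782), with CHS, chalcone synthase, at -3.76 ± 0.64. In iron homeostasis 7 of 9 fell and 1 rose (median -3.2, adjusted p = 0.647), with IMA3 at -4.4 ± 0.67 and the ferritin gene FER1 at 1.92 ± 0.35. Of 11 circadian clock genes 2 rose and 2 fell (median -0.26, mean 0.03, adjusted p = 0.932), with RVE8 at 2.08 ± 0.37. Of 9 root markers 5 fell and 1 rose (median -1.09, adjusted p = 0.659). Among 11 meristem and floral markers 7 fell and 1 rose (median -1.89, or -1.21 with absent genes at their bound, adjusted p = 0.438), with FT, the florigen gene, at -5.54 ± 0.56, SPL9 at -5 ± 0.25 and KNAT1 at 1.73 ± 0.12.

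At the ends of the ranking in DM1-DM2d, 4 genes without counts in Col-0 12 DAS stood out: AT5G38910 was at least 6330-fold higher, scpl14 at least 2800-fold, CYP71B9 at least 2260-fold and ADPG1, a polygalacturonase gene, at least 2040-fold. These bounds, and those below, set the empty group at 3 counts over the group. Set at 3 fragments of 2 mates they would be up to 2 times smaller. At the other end PDF1.2A (AT5G44420), a plant defensin gene, had no counts in DM1-DM2d against 10.5 ± 1.8 CPM in Col-0 12 DAS and was at least 922-fold lower, and BASL, a polarity gene of stomatal precursors, at least 328-fold lower. Upper-quartile scaling shifted the median log2 change of all genes by -0.302 in this contrast, and no list median changed sign under any scaling tried.

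The second comparison set DM6-DM7 against Col-0 14 DAS, 3 libraries each. The Col-0 14 DAS libraries differed more among themselves than those of any other group, by a chi-square per gene of 54 to 209 between pairs, against at most 27.6 elsewhere. A fit of these 6 libraries alone called 11226 genes in place of the 15124 below. PR1, named here after its values were seen, rose from 33.2 ± 17 CPM to 8620 ± 470 CPM (log2 change 8.02, SE 0.767). BIR1 rose by 2.28 ± 0.11 (adjusted p = 5.34e-11), ORE1 by 3.34 ± 0.17 and the EDS1 relative EDS1B (AT3G48080) by 5.02 ± 0.31. LHCA6 fell by 2.96 on the log2 scale (SE 0.14, adjusted p = 6.91e-11), and LHCB2.3 (AT3G27690) went from 3000 ± 880 to 119 ± 33 CPM, a change of -4.66 ± 0.31. In all 15124 of 23349 genes differed (8180 higher, 6944 lower), 8014 of them by at least 2-fold (3819 higher, 4195 lower). The share of the called genes that were higher was 54.1%, but 48% with RLE scaling, 47.9% with DESeq2 and 42.4% with upper-quartile scaling, which shifted the median of all genes by -0.178. More genes were lower than higher also without DM6-DM7 replicate 1 (7064 higher, 7314 lower), replicate 2 (6725 and 7149) or replicate 3 (6838 and 7209), and without Col-0 14 DAS replicate 2 (7232 and 7455) or replicate 3 (7298 and 7690). Which direction held more genes is not settled.

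All 10 genes of the helper NLR and EDS1 node rose in DM6-DM7 (median 1.96), as did 15 of 18 DM target loci (median 1.66), 19 of 20 salicylic acid genes (median 3.02) and 9 of 10 systemic acquired resistance genes (median 4.43). Adjusted p values were 2.1e-06, 3.97e-06, 1.14e-06 and 0.000187, and with an estimated correlation the adjusted p was 0.143, 0.159, 0.236 and 0.272. ADR1 rose by 2.19 ± 0.2, ADR1-L1 by 2.36 ± 0.14, and ADR1-L2 rose too (adjusted p = 2.62e-06). RPP7 (AT1G58602; chromosome 1, 21746354 to 21766048), the Col-0 relative of DM6, rose by 0.78 ± 0.11, its cluster neighbour AT1G58390 by 3.71 ± 0.48, and HR4, the Col-0 relative of DM7, by 3.74 ± 0.51. HR4 stood at 29.1, 166 and 47.3 CPM in the 3 Col-0 14 DAS libraries, and its change was 4.74 without replicate 2. The DM1 locus gene AT5G41750 rose by 3.39 ± 0.42. Among salicylic acid genes WRKY38 rose by 8.34 ± 0.54, WRKY54 by 4.69 ± 0.33 and NPR3 by 1.94 ± 0.12. AZI1 (AT4G12470) and EARLI1, lipid transfer protein genes of systemic resistance, rose by 5.17 ± 0.33 and 5.83 ± 0.49.

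In pattern-triggered immunity 22 of 26 genes rose and 2 fell (median 1.77, adjusted p = 6.2e-07, or 0.13 with an estimated correlation), with BIK1 at 2.47 ± 0.13, BAK1 at 1.12 ± 0.08 and PEPR1 at -1.62 ± 0.2. Of 18 NLR receptors 14 rose (median 0.68, adjusted p = 0.0125, or 0.507 with an estimated correlation), with ZAR1 at 1.27 ± 0.1, and adjusted over the list alone 14 rose and 1 fell. In ER protein folding 14 of 15 rose (median 1.37, adjusted p = 1.03e-07, or 0.159 with an estimated correlation), with the ER chaperone genes CRT3 at 2.47 ± 0.19 and HSP90.7 at 1.51 ± 0.11. In senescence 9 of 12 rose (median 1.11, adjusted p = 0.00302, or 0.16 with an estimated correlation), with PAO at 1.22 ± 0.1. The senescence median was 1.94 without Col-0 14 DAS replicate 1.

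All 19 light harvesting genes (median -1.91), 22 photosystem genes (median -1.67), 17 Calvin cycle genes (median -1.78) and 15 chlorophyll synthesis genes (median -1.52) fell in DM6-DM7, over all genes and adjusted over the list alone. The adjusted p values were 1.45e-11, 9.78e-17, 3.29e-17 and 9.32e-09, and with an estimated correlation the adjusted p was 0.169, 0.159, 0.13 and 0.13. PSBQ1 changed by -2.14 ± 0.12, SBPASE by -2 ± 0.1 and PORC, a protochlorophyllide reductase gene, by -1.97 ± 0.11. Plastid-encoded genes held 0.0443 ± 0.0023% of counts in DM6-DM7 and 0.106 ± 0.029% in Col-0 14 DAS (SD, n = 3), and 88 of 127 were lower (median -1.47).

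Of 31 cell cycle genes 28 fell and 2 rose (median -1.15, adjusted p = 4.7e-06, or 0.429 with an estimated correlation), with PCNA1 at -1.06 ± 0.1 and CYCD3;3 at 1.08 ± 0.1. Of 26 auxin genes 20 fell and 2 rose (median -2.36, adjusted p = 9.96e-05, or 0.301 with an estimated correlation), with IAA3 at -2.77 ± 0.23. Of 11 aliphatic glucosinolate genes 10 fell and 1 rose (median -1.15, adjusted p = 0.00296, or 0.419 with an estimated correlation), with MYB29 at -3.98 ± 0.34 and CYP79F2 at 1.33 ± 0.13. Of 9 anthocyanin genes 8 fell (median -4.66, adjusted p = 0.0291, or 0.6 with an estimated correlation), with CHS at -5.24 ± 0.65. All 9 stomatal lineage genes fell (median -2.5, adjusted p = 9.13e-06, or 0.13 with an estimated correlation), with EPFL9, the stomagen gene, at -3.62 ± 0.24. Without Col-0 14 DAS replicate 1 the anthocyanin median was -2.56 and CHS stood at -4.09. Without DM6-DM7 replicate 1 CHS stood at -6.08 and the stomatal lineage median was -3.53.

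Other lists did not pass camera in DM6-DM7. Of 27 jasmonate genes 6 rose and 11 fell (10 when adjusted over the list alone; median -0.39, adjusted p = 0.376), with AOS at -2.04 ± 0.09 and LOX2 at 2.16 ± 0.23. Of 14 genes of abscisic acid and cold response 10 fell (12 when adjusted over the list alone; median -2.71, adjusted p = 0.0824), with RD29A at -5.18 ± 0.63. Of 17 genes of cell wall expansion 11 fell (12 when adjusted over the list alone) and 4 rose (median -0.67, adjusted p = 0.0743), with EXPA5 at -4.12 ± 0.22 and XTH24 at 4.17 ± 0.33. KNAT1 rose by 2.65 ± 0.11. Among the genes at the ends of the ranking AT1G13550 was at least 373-fold higher and PDF1.2c at least 725-fold lower against an empty group, and GolS2, a galactinol synthase gene, changed by -8.33 ± 1.22. Without Col-0 14 DAS replicate 1 GolS2 stood at -5.87 and RD29A at -3.93.

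**Figure D2:**
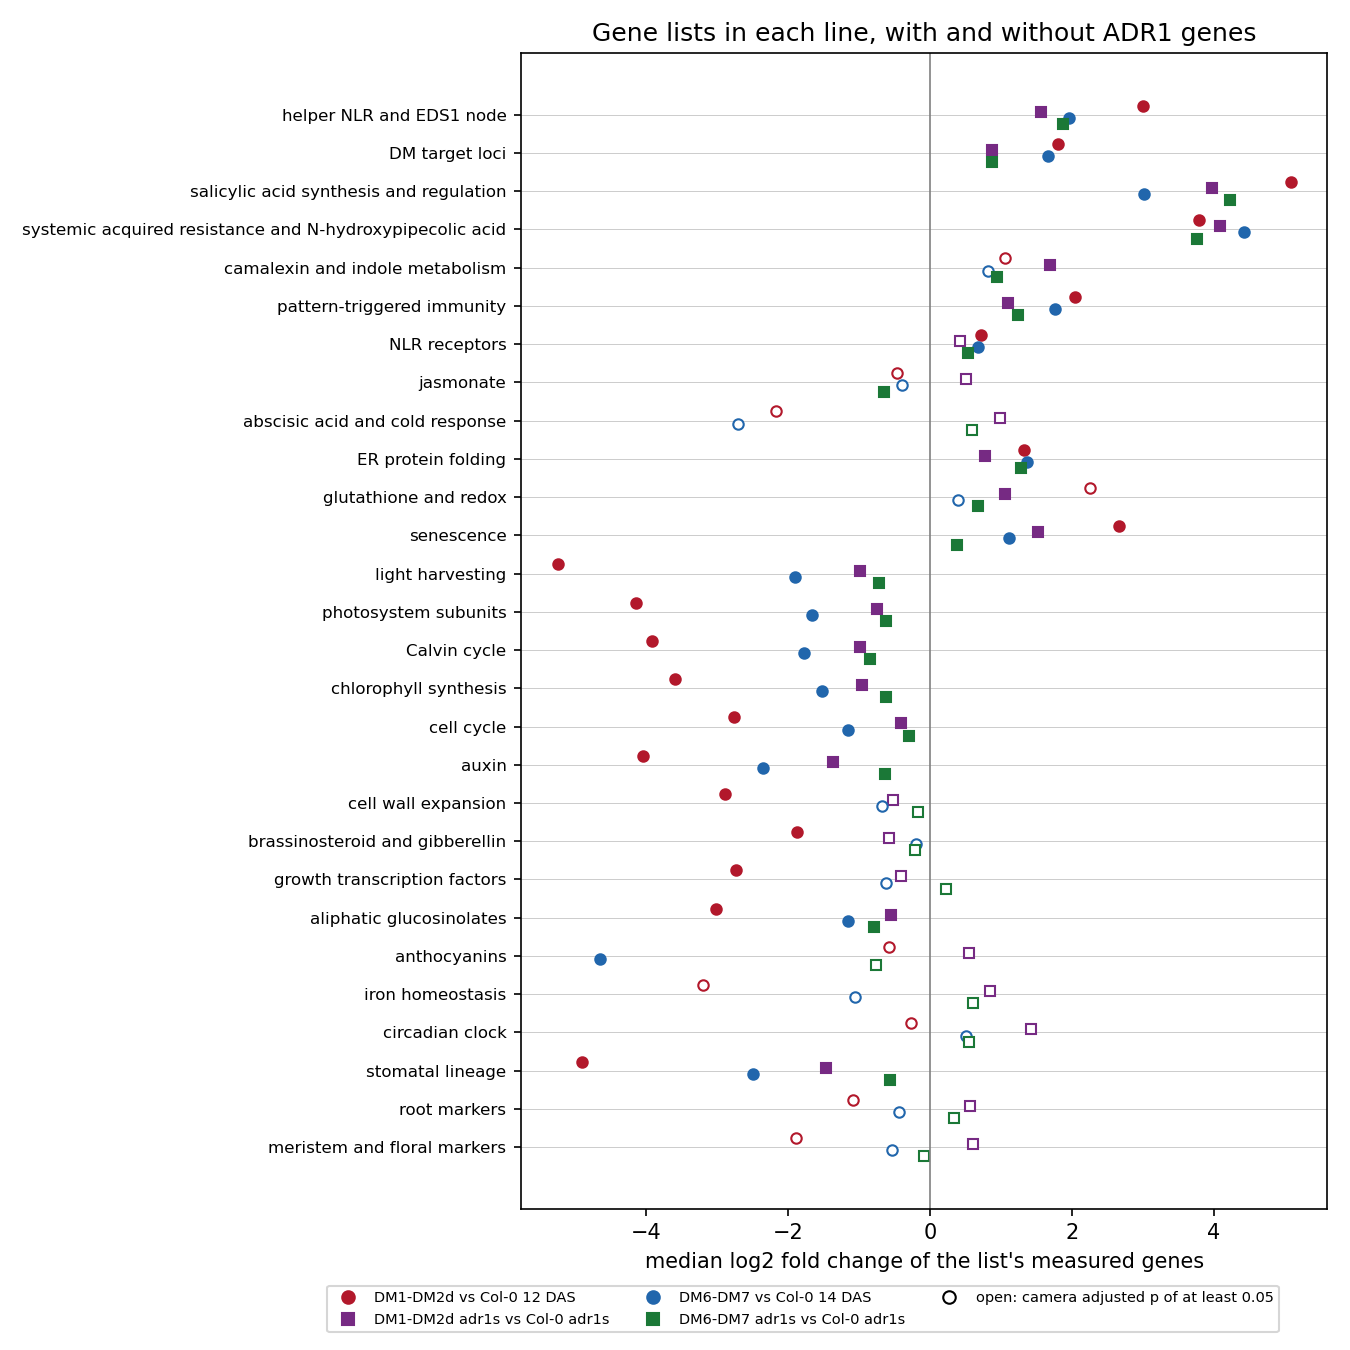
Median log2 fold change (horizontal axis) of the measured genes of each of the 28 lists in DM1-DM2d and DM6-DM7, each against its Col-0 group, with ADR1 genes intact and in adr1s; open symbols mark lists that did not pass camera. Light harvesting stood at -5.25 and -1.91 with ADR1 genes intact and at -0.98 and -0.72 in adr1s.

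Both lines changed many genes in the same direction. At 2-fold or more 2663 genes were higher in both, where independent calls would give 907.1, and 3300 were lower in both, where 1151 would be. Only 91 were higher in DM1-DM2d and lower in DM6-DM7, and 157 were the reverse. The odds ratios were 13.3 and 19 for a shared direction, across genes that are not independent replicates. Across the 23349 genes the log2 changes had a Pearson r of 0.641 and a Spearman rho of 0.692, as a description only.

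The difference between the lines was tested directly, as the DM1-DM2d effect minus the DM6-DM7 effect, each against its own Col-0 (11503 genes, 5145 above and 6358 below 0). The share above 0 was 44.7%, but 52.6% with RLE scaling (6195 above, 5576 below), 52.7% with DESeq2 (6452 and 5798) and 38.5% with upper-quartile scaling (4407 and 7052). The majority thus turned over with the scaling. Age and label batch also differ between the lines. NPR3 rose more in DM1-DM2d, by 2.44 ± 0.18 on the log2 scale, EDS1 (AT3G48090) by 1.82 ± 0.27 and PR1 by 3.03 ± 0.89, whereas AZI1 differed by -4.96 ± 0.42 and NIMIN3 by -1.98 ± 0.18. In the salicylic acid list 12 of 20 genes were above 0 and 1 below (median 1.67, adjusted p = 0.00302, or 0.462 with an estimated correlation). In the helper NLR list 7 of 10 were above 0 (median 0.77, adjusted p = 0.0135, or 0.395 with an estimated correlation). In glutathione and redox 6 of 12 were above 0 and 1 below (median 1.2, adjusted p = 0.0406, or 0.442 with an estimated correlation). Adjusted over the list alone, 13 salicylic acid genes were above 0 and the other 2 counts were the same. Without Col-0 12 DAS replicate 1 PR1 differed by 5.68 and the medians of the salicylic acid and glutathione lists were 2.42 and 1.89. Without its replicate 2 PR1 differed by 2.17 and the glutathione median was 0.72.

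For lists below 0 the median of the DM1-DM2d effect minus the DM6-DM7 effect was -3.37 for light harvesting (18 of 19 genes below 0), -2.5 for photosystem subunits (22 of 22), -2.18 for the Calvin cycle (17 of 17) and -1.75 for chlorophyll synthesis (11 of 15). It was -1.28 for the cell cycle (25 of 31 below 0, or 26 adjusted over the list alone), -2.29 for auxin (17 of 26), -1.34 for cell wall expansion (10 of 17), -1.62 for brassinosteroid and gibberellin (10 of 15), -2.61 for growth transcription factors (8 of 13, or 9 adjusted over the list alone), -1.86 for aliphatic glucosinolates (10 of 11) and -1.94 for the stomatal lineage (5 of 9, or 7 adjusted over the list alone). The adjusted p values ran from 6.97e-25 for photosystem subunits to 0.0413 for cell wall expansion, and with an estimated correlation the adjusted p ran from 0.13 to 0.525. LHCB5 differed by -3.38 ± 0.24, PRK, the phosphoribulokinase gene, by -2.89 ± 0.17, CYCD3;3 by -2.27 ± 0.15, AOC1 by -5.89 ± 0.36, GASA4 by -4.52 ± 0.15 and CYP79F2 by -4.06 ± 0.19, and LDOX, of anthocyanin synthesis, by 5.62 ± 1.27. HSP90.7 differed by -1.26 ± 0.17, and the clock genes TOC1 and RVE8 by -1.43 ± 0.23 and 3.01 ± 0.45. LDOX differed by 4.04 without Col-0 14 DAS replicate 1 and 6.33 without DM6-DM7 replicate 3, and the median of growth transcription factors was -1.9 without DM6-DM7 replicate 2. The medians of the DM target loci (0.06), NLR receptors (0.02) and jasmonate genes (-0.14) changed sign with the scaling, which shifted the median of all genes by up to 0.149.

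The third comparison gave the effect of DM1-DM2d without the ADR1 genes, 3 libraries against 3 of Col-0 adr1s. PR1 stood at 751 ± 240 CPM against 0.286 ± 0.22 CPM, a log2 change of 11.33 ± 0.92. Without Col-0 adr1s replicate 3 it was 12.19. SARD1 (AT1G73805), a transcription factor gene of salicylic acid synthesis, rose by 7.51 ± 0.63 and EDS1B by 5.58 ± 0.38, and LHCB2.3 fell by 2.41 on the log2 scale (SE 0.28) from 1350 ± 150 CPM to 253 ± 35 CPM. In all 9973 genes differed (5582 higher, 4391 lower), 3670 of them by at least 2-fold (2636 higher, 1034 lower).

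In DM1-DM2d adr1s 9 of 10 genes of the helper NLR and EDS1 node rose (median 1.57), 11 of 18 DM target loci (median 0.87), 19 of 20 salicylic acid genes with 1 lower (median 3.98) and 9 of 10 systemic acquired resistance genes (median 4.09). Their adjusted p, in order, was 5.02e-10, 0.000638, 2.66e-13 and 4.08e-08, and with an estimated correlation the adjusted p was 0.13, 0.248, 0.13 and 0.159. ADR1 rose by 2.63 ± 0.21, ADR1-L1 by 0.87 ± 0.14 and ADR1-L2 by 0.69 ± 0.17, AT5G41750 by 5.56 ± 0.48, AT3G44400 by 2.23 ± 0.14 and HR4 by 2.9 ± 0.49, and HR2 was at 1.22 ± 0.9 (adjusted p = 0.298). The median of the DM target loci was 0.42 without DM1-DM2d adr1s replicate 3. WRKY54 rose by 5.54 ± 0.39 and AZI1 by 3 ± 0.3. In camalexin and indole metabolism 13 of 16 rose and 1 fell (median 1.69, adjusted p = 1.25e-05, or 0.159 with an estimated correlation), with PEN3 at 2.05 ± 0.22, MYB51 at 2.6 ± 0.28 and CYP79B3 at -0.85 ± 0.23. In pattern-triggered immunity 19 of 26 rose (20 when adjusted over the list alone) and 1 fell (median 1.1, adjusted p = 1.1e-08, or 0.13 with an estimated correlation), with BIR1 at 1.93 ± 0.11, SOBIR1 at 2.28 ± 0.2 and PEPR1 at -0.9 ± 0.2.

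ER protein folding (14 of 15 higher, 15 adjusted over the list alone, median 0.78), glutathione and redox (6 of 12 higher, 1 lower, median 1.06) and senescence (8 of 12 higher, 1 lower, median 1.53) rose too in DM1-DM2d adr1s. Their adjusted p values were 3.31e-06, 0.00484 and 0.000968, and 0.228, 0.275 and 0.143 with an estimated correlation. PDIL1-1 rose by 1.61 ± 0.18, PRX34 by 4.46 ± 0.26 and ORE1 by 2.58 ± 0.17, whereas the catalase gene CAT2 changed by -1.23 ± 0.18 and SEN1 by -1.11 ± 0.22. Of 27 jasmonate genes 12 rose and 4 fell (median 0.51, adjusted p = 0.169), with LOX2 at 2.5 ± 0.23 and AOC3 at 2.41 ± 0.29.

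In light harvesting 17 of 19 genes fell in DM1-DM2d adr1s (18 when adjusted over the list alone, median -0.98), in photosystem subunits 22 of 22 (median -0.75), in the Calvin cycle 17 of 17 (median -0.99) and in chlorophyll synthesis 11 of 15 (12 when adjusted over the list alone, median -0.96). The adjusted p values were 2.27e-09, 7.44e-10, 1.55e-15 and 4.48e-08, and with an estimated correlation the adjusted p was 0.228, 0.272, 0.134 and 0.13. Rubisco activase, RCA (AT2G39730), changed by -1.23 ± 0.12 and CAO by -1.3 ± 0.13. Plastid-encoded genes held 0.11 ± 0.052% of counts against 0.092 ± 0.0094% in Col-0 adr1s (SD, n = 3), with 3 of 127 higher and 4 lower. In the cell cycle 13 of 31 fell and 2 rose (median -0.41), in auxin 16 of 26 fell (17 when adjusted over the list alone) and 2 rose (median -1.37), in aliphatic glucosinolates 9 of 11 fell (median -0.55; adjusted over the list alone 1 rose also) and in the stomatal lineage all 9 fell (median -1.46). These had adjusted p values of 0.00535, 4.86e-05, 0.0106 and 9.96e-05, and 0.627, 0.269, 0.475 and 0.159 with an estimated correlation. CYCD3;2 changed by -0.77 ± 0.09, IAA3 by -1.82 ± 0.22, MAM1 by -0.55 ± 0.12 and TMM by -1.61 ± 0.19. The clock genes LUX, TOC1 and RVE8 changed by 1.56 ± 0.17, 1.43 ± 0.16 and -1.78 ± 0.27.

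At the top of this ranking AT2G44240 was at least 1330-fold higher than in Col-0 adr1s, where it had no counts. At the bottom AT1G53440 (chromosome 1, 19945869 to 19951562) changed by -5.99 ± 0.22 and AT5G62710 (chromosome 5, 25187221 to 25190722) by -5.33 ± 0.31, and both were also lower in DM1-DM2d with ADR1 genes intact.

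The fourth comparison gave the effect of DM6-DM7 without the ADR1 genes, against the same 3 Col-0 adr1s libraries. PR1 stood at 1080 ± 280 CPM (log2 change 11.85 ± 0.93), SARD1 rose by 7.6 ± 0.64, EDS1B by 6.09 ± 0.38 and CRT3 by 2.29 ± 0.19, and LHCB2.3 fell by 2.09 on the log2 scale (SE 0.28) to 316 ± 95 CPM. PR1 changed by 12.71 without Col-0 adr1s replicate 3. In all 7290 genes differed (4339 higher, 2951 lower), 2339 of them by at least 2-fold (1751 higher, 588 lower).

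In DM6-DM7 adr1s 9 of 10 genes of the helper NLR and EDS1 node rose (median 1.87), 12 of 18 DM target loci (median 0.88), 18 of 20 salicylic acid genes (19 when adjusted over the list alone) with 1 lower (median 4.23) and 10 of 10 systemic acquired resistance genes (median 3.77). In order, the adjusted p was 2.26e-16, 7.27e-08, 1.39e-18 and 1.81e-11, and with an estimated correlation the adjusted p was 0.0554, 0.13, 0.13 and 0.13. ADR1 rose by 1.9 ± 0.2 and ADR1-L1 by 1.88 ± 0.14, and ADR1-L2 stood at 0.05 ± 0.17 (adjusted p = 0.862). HR4 rose by 3.48 ± 0.5, RPP7 by 0.62 ± 0.11 and AT1G58390 by 2.62 ± 0.48. Without Col-0 adr1s replicate 3 AT1G58390 stood at 3.39. WRKY54 rose by 5.47 ± 0.39, CBP60G, a relative of SARD1, by 4.22 ± 0.38, PR5 by 3.59 ± 0.28 and SARD4 by 2.59 ± 0.31. In pattern-triggered immunity 20 of 26 rose (21 when adjusted over the list alone) and 1 fell (median 1.24, adjusted p = 2.52e-15, or 0.0554 with an estimated correlation), with BIR1 at 2 ± 0.11 and SOBIR1 at 2.94 ± 0.2. Of 18 NLR receptors 14 rose and 2 fell (median 0.53, adjusted p = 0.000471, or 0.357 with an estimated correlation), with ZAR1 at 0.94 ± 0.1. In ER protein folding 15 of 15 rose (median 1.28, adjusted p = 1.26e-18, or 0.117 with an estimated correlation), with HSP90.7 at 1.3 ± 0.11.

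Camalexin and indole metabolism (7 of 16 higher, 2 lower, or 11 and 3 adjusted over the list alone, median 0.95), glutathione and redox (5 of 12 higher, 1 lower, median 0.68) and senescence (6 of 12 higher, or 7 adjusted over the list alone, 1 lower, median 0.38) passed camera in DM6-DM7 adr1s. Their adjusted p values were 0.00413, 0.00996 and 0.0138, and 0.322, 0.335 and 0.231 with an estimated correlation. MYB51 rose by 2.19 ± 0.28, PRX34 by 3.57 ± 0.25 and ORE1 by 1.91 ± 0.17, and CAT2 changed by -1.3 ± 0.18. Jasmonate genes fell in balance, 13 of 27 lower and 4 higher (median -0.65, adjusted p = 0.00138, or 0.173 with an estimated correlation), with AOS at -1.12 ± 0.09, the repressor gene JAZ10 at -2.09 ± 0.24 and AOC3 at 1.82 ± 0.29.

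Light harvesting (17 of 19 lower, median -0.72), photosystem subunits (22 of 22, median -0.62), the Calvin cycle (17 of 17, median -0.84) and chlorophyll synthesis (12 of 15, median -0.62) fell in DM6-DM7 adr1s, with the same counts adjusted over the list alone. The adjusted p was, in turn, 7.32e-09, 6.78e-11, 9.78e-17 and 4.42e-07, and with an estimated correlation the adjusted p was 0.231, 0.246, 0.13 and 0.143. SBPASE changed by -0.97 ± 0.1, PRK by -1 ± 0.11 and CAO by -1.05 ± 0.13. Plastid-encoded genes held 0.0664 ± 0.015% of counts (SD, n = 3), and 9 of 127 were lower. Smaller shifts passed camera in the cell cycle (7 of 31 lower, 6 adjusted over the list alone, 2 higher, median -0.29), auxin (6 of 26 lower, 2 higher, median -0.64), aliphatic glucosinolates (9 of 11 lower, 1 higher, median -0.79) and the stomatal lineage (2 of 9 lower, median -0.57). These had adjusted p values of 0.0179, 0.029, 8.85e-06 and 0.0242, and 0.679, 0.542, 0.231 and 0.398 with an estimated correlation. MCM7 changed by -0.49 ± 0.11, MAM1 by -0.92 ± 0.12 and EPFL9 by -1.1 ± 0.22. None of the 9 anthocyanin and 14 abscisic acid and cold response genes was called (medians -0.76 and 0.6), with CHS at -1.36 ± 0.56 (adjusted p = 0.0776) and COR47 at -0.45 ± 0.23 (adjusted p = 0.161). AT2G44240 was at least 793-fold higher than in Col-0 adr1s, and AT3G01345 (chromosome 3, 129138 to 130749) changed by -9.59 ± 0.4.

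**Figure D3:**
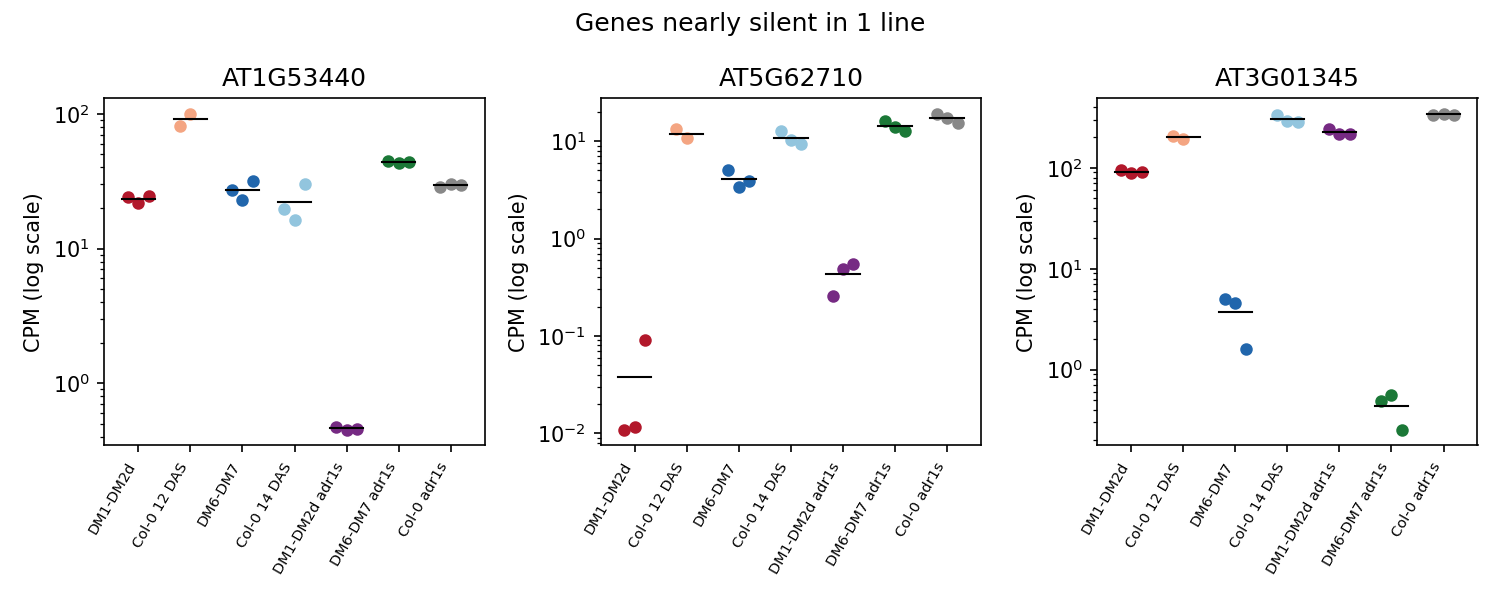
CPM (log axis) of AT1G53440, AT5G62710 and AT3G01345 in each of the 20 libraries, 1 point per library, with a line at the mean of each group. AT1G53440 and AT5G62710 averaged 0.461 and 0.432 CPM in DM1-DM2d adr1s, and AT3G01345 averaged 0.436 CPM in DM6-DM7 adr1s.

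Part of each response was also called without the ADR1 genes. Of the 5546 genes at least 2-fold higher in DM1-DM2d, 3056 (55.1%) were called higher in DM1-DM2d adr1s, 206 (3.71%) were called lower there, and the median went from 2.11 over the set with ADR1 genes intact to 0.63 in adr1s. Of the 6408 lower genes 2679 (41.8%) were called lower and 421 (6.57%) higher, with medians of -2.48 and -0.43. In DM6-DM7, 2380 of 3819 higher genes (62.3%) and 1617 of 4195 lower genes (38.5%) were called the same way in adr1s and 17 and 11 the opposite way, with medians going from 2.19 to 1 and from -1.85 to -0.55. The sets were picked for a large change with ADR1 genes intact, which by itself makes the second median smaller, so these medians do not give the size of a loss. The percentages depend on the power in adr1s, which the simulated data, with few changed genes, do not give.

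The difference was tested directly, over all genes, as the effect of each pair minus its effect in adr1s, a contrast in which an additive batch shift cancels. The ADR1 state coincides with label batch and the age of the adr1s plants is not given, so an age or a preparation that changes the size of a response does not cancel. For DM1-DM2d 13658 genes passed (6067 above and 7591 below 0, so 44.4% above, or 33.7% with upper-quartile scaling, which shifted the median of all genes by -0.276). ADR1-L1 and ADR1-L2 rose more with ADR1 genes intact, by 1.91 ± 0.21 and 1.46 ± 0.26, and ADR1 was at 0.5 ± 0.3 (adjusted p = 0.162). NPR3 rose more by 3.06 ± 0.19, and SGR1 by 4.14 ± 0.34, but NIMIN3 differed by -1.57 ± 0.18 and AZI1 by -2.8 ± 0.41. LHCA6 fell further by -4.29 ± 0.22, HCEF1 by -3.64 ± 0.16, CYCB1;2 by -3.17 ± 0.32, AOC1 by -7.48 ± 0.37 and GASA4 by -4.54 ± 0.15. The lower end of the ranking held AACT1 at -13.81 ± 1.38, or -15.08 without DM1-DM2d replicate 1 and -14.45 without Col-0 adr1s replicate 3. At the upper end MAP18, a microtubule-associated protein gene, had 2 counts over Col-0 12 DAS, too few for a size.

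Of the lists, the helper NLR and EDS1 node (7 of 10 above 0, median 1.26), the DM target loci (7 of 18 above, 1 below, median 0.83), salicylic acid (8 of 20 above, or 7 adjusted over the list alone, 1 below, median 1.1), pattern-triggered immunity (10 of 26 above, 1 below, median 0.58) and senescence (7 of 12 above, 1 below, median 0.97) rose more in DM1-DM2d than in DM1-DM2d adr1s. Adjusted p was 0.0153, 0.0426, 0.0236, 0.0241 and 0.0275, and 0.398, 0.507, 0.575, 0.39 and 0.272 with an estimated correlation. The helper list holds the edited genes, here and for DM6-DM7, and is not given without them. Below 0 were light harvesting (19 of 19, median -4.29), photosystem subunits (22 of 22, median -3.43), the Calvin cycle (17 of 17, median -3), chlorophyll synthesis (12 of 15, median -2.64), the cell cycle (30 of 31, median -2.46), auxin (17 of 26, median -3.04), cell wall expansion (9 of 17, median -1.83), growth transcription factors (11 of 13, median -2.51), aliphatic glucosinolates (11 of 11, median -2.47) and the stomatal lineage (8 of 9, median -3.45). Their adjusted p ran from 1.33e-28 for photosystem subunits to 0.0428 for cell wall expansion, and from 0.13 to 0.507 with an estimated correlation. The medians of ER protein folding (-0.03) and of glutathione and redox (0.17) changed sign with the scaling. The salicylic acid median was 1.73 and 0.7 without Col-0 12 DAS replicate 1 and 2, and that of the DM target loci 0.38 without Col-0 adr1s replicate 3.

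For DM6-DM7 the same contrast called 7277 genes (3478 above and 3799 below 0, so 47.8% above, or 38% with RLE scaling and 29% with upper-quartile scaling, which shifted the median of all genes by -0.162). The number above 0 was 2015 without DM6-DM7 replicate 2, 2172 without its replicate 3, 2008 without DM6-DM7 adr1s replicate 1 and 2146 without its replicate 2. Without Col-0 14 DAS replicate 1 more genes lay above 0 (3937) than below (3815). ADR1-L2 rose more by 1.29 ± 0.24, and ADR1 and ADR1-L1 were at 0.29 ± 0.28 and 0.48 ± 0.19 (adjusted p = 0.466 and 0.0666). NPR3 rose more by 0.89 ± 0.17, ORE1 by 1.43 ± 0.23, AZI1 by 3.35 ± 0.4 and KNAT1 by 1.96 ± 0.14. AT1G22110 also passed above 0, with 2 counts over Col-0 14 DAS, too few for a size. PR1 and SARD1 went the other way, at -3.83 ± 0.96 and -3.37 ± 0.76, over the low Col-0 adr1s levels of 0.286 ± 0.22 and 0.247 ± 0.097 CPM. PSBQ1 was at -1.41 ± 0.16, CYCA3;1 at -1.55 ± 0.24, RD29A at -4.4 ± 0.78, CHS at -3.87 ± 0.8 and EPFL9 at -2.52 ± 0.31. Without Col-0 14 DAS replicate 1 RD29A was at -3.15 and CHS at -2.72, without DM6-DM7 replicate 1 CHS was at -4.71, and without Col-0 adr1s replicate 3 PR1 was at -4.69. The DM target loci (5 of 18 above 0, 1 below, median 0.69) and senescence (4 of 12 above, median 0.46) passed with adjusted p values of 0.0112 and 0.00942, and 0.398 and 0.227 with an estimated correlation. The median of the DM target loci was 0.4 without Col-0 adr1s replicate 3. That of senescence was 1.27 without Col-0 14 DAS replicate 1 and 0.26 without its replicate 3.

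Below 0 in DM6-DM7 were light harvesting (16 of 19, or 18 adjusted over the list alone, median -1.16), photosystem subunits (22 of 22, median -1.02), the Calvin cycle (15 of 17, or 16 adjusted over the list alone, median -0.88), chlorophyll synthesis (11 of 15, median -0.86), the cell cycle (21 of 31, or 22 adjusted over the list alone, 1 above, median -0.84), auxin (16 of 26, or 17 adjusted over the list alone, median -1.41), cell wall expansion (6 of 17, or 8 adjusted over the list alone, 4 above, median -0.43), abscisic acid and cold response (8 of 14, or 12 adjusted over the list alone, median -3.97), anthocyanins (8 of 9, median -3.87) and the stomatal lineage (9 of 9, median -1.9). Their adjusted p values ran from 2.66e-13 for photosystem subunits to 0.029 for cell wall expansion, and from 0.13 to 0.542 with an estimated correlation. Without Col-0 14 DAS replicate 1 the medians of abscisic acid and cold response and of anthocyanins were -1.56 and -1.97. Without DM6-DM7 replicate 1 those of cell wall expansion and the stomatal lineage were -0.77 and -2.67. The helper NLR and EDS1 node (1 of 10 above 0, median 0.17, adjusted p = 0.641) and the salicylic acid list (4 of 20 above, 2 below, median -0.72, adjusted p = 0.824) did not pass. The medians of pattern-triggered immunity (0.07), NLR receptors (0.16), jasmonate (0.09), brassinosteroid and gibberellin (0.01) and the circadian clock (0.04) changed sign with the scaling.

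In the knockout the lines shared 3712 genes called higher and 2428 called lower, where independent calls would give 1037 and 555, and 22 and 9 genes went in opposite directions. The contrasts share their control libraries, which alone gave a Pearson r of 0.506 across genes in simulated data without any effect, against 0.779 measured. An r from noise alone and an r that holds effects are not on the same scale. The covariance was 0.146 on average in the simulations and 1.47 measured. No gene was called in the same direction in both contrasts in any of the 20 simulations.

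DM1-DM2d adr1s was then compared directly with DM6-DM7 adr1s, 3 libraries each within 1 label batch. Jasmonate genes were higher with DM1-DM2d: 16 of 27 (20 when adjusted over the list alone), none lower, median 1.11 (adjusted p = 2.26e-17, and 0.0121 with an estimated correlation). AOS differed by 1.11 ± 0.09, AOC1 by 1.69 ± 0.22 and AOC2 by 2.11 ± 0.29. The clock gene ELF4 was higher by 3.38 ± 0.49, LUX by 1.01 ± 0.17, the cold- and light-regulated gene COR27 by 6.07 ± 0.64 and FT by 2.66 ± 0.45, while HSP90.7 differed by -0.7 ± 0.11, TMM by -1.04 ± 0.18 and CYCD3;2 by -0.54 ± 0.09. ELF4 was higher by 2.49 and COR27 by 5.36 without DM1-DM2d adr1s replicate 3. AT3G01345 was higher by 9.01 ± 0.39 with DM1-DM2d, AT1G53440 lower at -6.57 ± 0.22 and AT5G62710 at -5.05 ± 0.31. ADR1-L1 differed by -1.01 ± 0.14. Of 20 salicylic acid genes 1 was called, lower (median -0.04, adjusted p = 0.83), and of 22 photosystem genes none was (median -0.06, adjusted p = 0.154), with PSBO1 at -0.1 ± 0.14 (adjusted p = 0.72).

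Other lists that passed camera here were camalexin and indole metabolism (4 of 16 higher, or 7 adjusted over the list alone, median 0.51), senescence (4 of 12 higher, or 5, median 0.35), anthocyanins (0 of 9 called, median 1.28), the circadian clock (4 of 11 higher, median 0.31) and meristem and floral markers (2 of 11 higher, or 3, median 0.39). Lower were ER protein folding (7 of 15, or 10 adjusted over the list alone, median -0.46), light harvesting (0 of 19 called, median -0.3), the Calvin cycle (1 of 17, median -0.16), chlorophyll synthesis (3 of 15, median -0.25), auxin (3 of 26, median -0.65), cell wall expansion (2 of 17, median -0.24), growth transcription factors (3 of 13, or 4, median -0.42) and the stomatal lineage (1 of 9, or 6, median -0.71). The adjusted p of these lists ran from 1.6e-07 for ER protein folding to 0.0349 for the Calvin cycle, and from 0.13 to 0.657 with an estimated correlation. Without DM1-DM2d adr1s replicate 1 the medians of the Calvin cycle and chlorophyll synthesis were -0.3 and -0.39, without replicate 2 that of anthocyanins was 0.78, and without replicate 3 that of the clock was 0.13. In all 2080 genes differed (1265 higher, 815 lower), 634 of them by at least 2-fold. This count fell to 994 without DM1-DM2d adr1s replicate 2, 1320 without its replicate 3, 1081 without DM6-DM7 adr1s replicate 1 and 1088 without its replicate 2, and the 1265 higher genes to 840 without DM1-DM2d adr1s replicate 1.

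Col-0 groups of different label batches were compared to size the difference between batches, where age or knockout and batch cannot be told apart. Col-0 adr1s differed from Col-0 12 DAS in 11151 genes (5380 higher, 5771 lower) and from Col-0 14 DAS in 9068 (4144 higher, 4924 lower), and the wild-type groups differed from each other in 12075 (5898 higher and 6177 lower at 14 DAS). In Col-0 adr1s PR1 differed by -5.22 ± 0.82 from Col-0 12 DAS and by -6.83 ± 0.81 from Col-0 14 DAS, SARD1 by -5.87 ± 0.64 and -4.6 ± 0.61, and ADR1-L2 by -1.44 ± 0.19 and -1.39 ± 0.17. Against Col-0 12 DAS, PR1 differed by -2.64 and SARD1 by -4.92 without its replicate 1, and by -6.14 and -6.5 without its replicate 2. Without Col-0 adr1s replicate 3 PR1 differed by -6.08 from Col-0 12 DAS and -7.69 from Col-0 14 DAS. In the salicylic acid list 15 of 20 genes were lower and 1 higher against Col-0 12 DAS (median -1.66), and 12 lower against Col-0 14 DAS (median -1.89). Between the wild types TOC1 differed by -4.24 ± 0.19, LUX by -3.5 ± 0.19 and RVE8 by 5.96 ± 0.41, all clock genes, and RCA by 3.53 ± 0.16. The wild types differed in 6579 genes, and Col-0 adr1s from Col-0 14 DAS in 5337, when fitted with the libraries of the contrast alone.

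**Figure D4:**
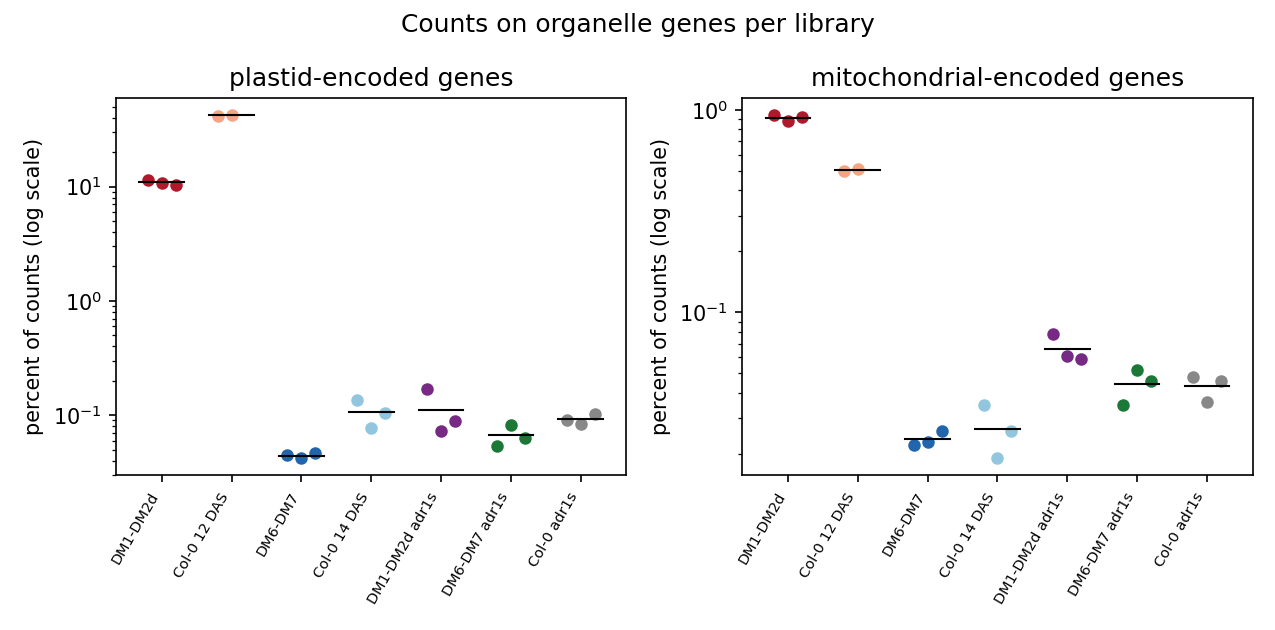
Percent of counts on plastid-encoded and mitochondrial genes (log axes) in each of the 20 libraries, 1 point per library, with a line at the mean of each group. The plastid share averaged 42% in Col-0 12 DAS and 10.9% in DM1-DM2d, and at most 0.11% in the other groups.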

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

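The tests of plastid-encoded transcripts, of salicylic acid genes in Col-0 adr1s and of nearly silent genes, and the regrouping by ADR1 state, were chosen after the results were seen, and the other tests here before. Differences of effects were tested as such, genes with edgeR and lists with camera at a preset correlation; no list difference in the next 3 paragraphs passed with an estimated correlation. The ADR1 state and label batch coincide in the differences from adr1s.

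For DM1-DM2d the effect differed from its effect in adr1s in 13658 genes. Single genes differed by 1.91 (ADR1-L1), 1.46 (ADR1-L2), 3.06 (NPR3) and 4.14 (SGR1) on the log2 scale, and by -1.57 (NIMIN3), -2.8 (AZI1), -4.29 (LHCA6), -3.64 (HCEF1), -3.17 (CYCB1;2), -7.48 (AOC1), -4.54 (GASA4) and -13.81 (AACT1). MAP18, with 2 counts over Col-0 12 DAS, had a fitted 9.71, which is no size. List medians were 1.26 (helper NLR and EDS1 node, edited genes included), 0.83 (DM target loci), 1.1 (salicylic acid), 0.58 (pattern-triggered immunity) and 0.97 (senescence). They were -4.29 (light harvesting), -3.43 (photosystem subunits), -3 (Calvin cycle), -2.64 (chlorophyll synthesis) and -2.46 (cell cycle). Others were -3.04 (auxin), -1.83 (cell wall expansion), -2.51 (growth transcription factors), -2.47 (aliphatic glucosinolates) and -3.45 (stomatal lineage). With an estimated correlation the adjusted p of these lists was 0.13 to 0.575. The salicylic acid median was 1.73 and 0.7 without Col-0 12 DAS replicate 1 and 2, and that of the DM target loci 0.38 without Col-0 adr1s replicate 3.

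For DM6-DM7 the effect differed from its effect in adr1s in 7277 genes. Single genes differed by 1.29 (ADR1-L2), 0.89 (NPR3), 3.35 (AZI1), 1.43 (ORE1) and 1.96 (KNAT1), and by -3.37 (SARD1), -3.83 (PR1), -1.41 (PSBQ1), -1.55 (CYCA3;1), -4.4 (RD29A), -3.87 (CHS) and -2.52 (EPFL9). AT1G22110, with 2 counts over Col-0 14 DAS, had a fitted 7.76, no size either. List medians were 0.69 for the DM target loci, 0.46 for senescence, -3.97 for abscisic acid and cold response, -1.16 for light harvesting, -1.02 for photosystem subunits, -0.88 for the Calvin cycle, -0.86 for chlorophyll synthesis, -0.84 for the cell cycle, -1.41 for auxin, -0.43 for cell wall expansion, -3.87 for anthocyanins and -1.9 for the stomatal lineage. Their adjusted p was 0.13 to 0.542 with an estimated correlation. Without Col-0 14 DAS replicate 1 the medians of abscisic acid and cold response, anthocyanins and senescence were -1.56, -1.97 and 1.27, and RD29A and CHS differed by -3.15 and -2.72. Other medians that moved were those of senescence (0.26 without Col-0 14 DAS replicate 3), the DM target loci (0.4 without Col-0 adr1s replicate 3), cell wall expansion and the stomatal lineage (-0.77 and -2.67 without DM6-DM7 replicate 1). CHS differed by -4.71 without DM6-DM7 replicate 1, and PR1 by -4.69 without Col-0 adr1s replicate 3.

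The DM1-DM2d effect differed from the DM6-DM7 effect in 11503 genes. Single genes differed by 2.44 (NPR3), 1.82 (EDS1), 3.03 (PR1), 5.62 (LDOX) and 3.01 (RVE8), and by -1.98 (NIMIN3), -4.96 (AZI1), -3.38 (LHCB5), -2.89 (PRK), -2.27 (CYCD3;3), -5.89 (AOC1), -1.26 (HSP90.7), -4.06 (CYP79F2), -1.43 (TOC1), -13.27 (IPS1) and -4.52 (GASA4). List medians were 0.77 for the helper NLR and EDS1 node, 1.67 for salicylic acid, 1.2 for glutathione and redox, -3.37 for light harvesting, -2.5 for photosystem subunits, -2.18 for the Calvin cycle, -1.75 for chlorophyll synthesis, -1.28 for the cell cycle, -2.29 for auxin, -1.34 for cell wall expansion, -1.62 for brassinosteroid and gibberellin, -2.61 for growth transcription factors, -1.86 for aliphatic glucosinolates and -1.94 for the stomatal lineage. An estimated correlation gave them an adjusted p of 0.13 to 0.525. Without Col-0 12 DAS replicate 1 the medians of salicylic acid and of glutathione and redox were 2.42 and 1.89 and PR1 differed by 5.68. Without its replicate 2 the glutathione median was 0.72 and PR1 differed by 2.17. LDOX differed by 4.04 without Col-0 14 DAS replicate 1 and 6.33 without DM6-DM7 replicate 3, and the median of growth transcription factors was -1.9 without DM6-DM7 replicate 2.

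Splits of 3 against 3 libraries are too few for a share under 0.05, with 10 splits each. The real split was the 1 with the most genes in each case: 15124 in DM6-DM7 against Col-0 14 DAS (highest other 8), 9973 in DM1-DM2d adr1s (highest other 0), 7290 in DM6-DM7 adr1s (highest other 0), 2080 between the lines in adr1s (highest other 1) and 9068 between Col-0 adr1s and Col-0 14 DAS (highest other 4). For the DM6-DM7 difference of effects, line and Col-0 were drawn anew within each ADR1 state in 50 of 200 splits. Of these 5, the real one included, gave as many genes as the real 7277 (highest other 12593), so chance was not excluded this way. The highest kept DM6-DM7 apart from Col-0 14 DAS and mixed the adr1s libraries, so it carried the whole DM6-DM7 effect, a structure of the samples. A regrouping with the ADR1 state drawn anew within the line and within Col-0 (2 of 50 gave as many, highest other 9888) decides nothing: the state coincides with label batch, so nearly all other splits mix batches within groups, and their median was 0 genes.

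The lower plastid share in DM1-DM2d than in Col-0 12 DAS (10.9% against 42%) was weighed first. A loss of RNA without a poly(A) tail would lower mitochondrial transcripts as well, but the ratio of mitochondrial to nuclear counts was higher in DM1-DM2d in each of 6 library pairs, by a factor of at least 1.11. The median change of plastid-encoded genes in DM6-DM7 was -1.47 (88 of 127 lower, none higher), but on at most 0.136% of a library's counts. This cannot tell whether preparation made the gap in label batch 1. A lower level of plastid transcripts in both lines with ADR1 genes intact is a hypothesis that these data allow, beside preparation. It was found and tested on the same libraries.

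The salicylic acid list did not pass camera in the DM6-DM7 effect minus its effect in adr1s (4 of 20 genes above 0, 2 below, median -0.72, adjusted p = 0.824), which does not show that the 2 effects were equal. Counts near 0 in Col-0 adr1s could raise the fold changes there: over the 11 members with at least 2 CPM in that group the median was 0.06 with a standard error of 0.32, which leaves this open. Raised immune expression in 1 Col-0 14 DAS library could lower the other side, and without each in turn the median was -0.81, -0.18 and -1.01, the highest with a standard error of 0.44, so this stays open too; the use of that standard error was decided after the median was seen. The list was lower in Col-0 adr1s than in Col-0 14 DAS (median -1.89) and Col-0 12 DAS (-1.66), and by -0.46 between the wild types. An ADR1 effect on the baseline and label batch 3 cannot be told apart, since no Col-0 with ADR1 genes lies in that batch.

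A few genes were nearly silent in 1 of the adr1s lines. AT1G53440 was at 0.461 ± 0.011 CPM in DM1-DM2d adr1s against 29.5 ± 0.8 in Col-0 adr1s, AT5G62710 at 0.432 ± 0.15 against 17.3 ± 1.8, and AT3G01345 at 0.436 ± 0.16 in DM6-DM7 adr1s against 338 ± 4.3 (SD, n = 3). Of the 60 nearest measured genes 2 (3.33%) were called and at least 2-fold lower. This speaks only to a wide loss, not to other local changes. A change carried by the line since before the knockout is a candidate explanation for AT5G62710, at -8.25 ± 0.41 in DM1-DM2d with ADR1 genes intact, and for AT3G01345, at -6.36 ± 0.33 in DM6-DM7. For AT1G53440 the nearly silent state was not present in DM1-DM2d with ADR1 genes intact, where its 3 libraries had 21.8 to 24.4 CPM. These values argue against a silent state carried since before the knockout for this gene. Its change of -1.96 ± 0.18 there was against 90.9 ± 13 CPM in Col-0 12 DAS. Whether a smaller change was carried stays open.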

How the results depend on the processing

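The fits without plastid and mitochondrial genes and with counts halved were chosen after seeing the data. All alternatives planned were run. No called named gene reversed its direction under them, and no list that passed camera passed in the opposite direction with RLE scaling, the block, fry or an estimated correlation. Medians near 0 of lists that had not passed changed sign with the scaling. Of 960 medians of lists that had passed, with each replicate left out, 0 changed sign; these medians were added after seeing the data, and camera was not run again for them. The balance of genes above and below 0 turned over with the scaling in DM1-DM2d (8555 and 8490, or 6974 and 10032 with upper quartile), DM6-DM7 (8180 and 6944, or 7175 and 7782 with RLE), the DM1-DM2d effect minus the DM6-DM7 effect (5145 and 6358, or 6195 and 5576 with RLE) and between the wild types (5898 and 6177, or 6178 and 5848 with RLE). It also turned over with 1 library left out in DM1-DM2d, DM6-DM7, the DM6-DM7 effect minus its effect in adr1s and between the wild types, and with only the libraries of the contrast in the fit in DM1-DM2d (8781 and 9087), DM6-DM7 adr1s (4796 and 4842) and between the wild types (3535 and 3044). The same happened without plastid and mitochondrial genes and with counts halved in DM1-DM2d, DM6-DM7 and between the wild types, with DESeq2 in DM6-DM7, between the wild types and in the difference between lines, with the block between the wild types, at an adjusted p of 0.01 between the wild types and in Col-0 adr1s against Col-0 12 DAS, and at 2-fold in DM1-DM2d, DM6-DM7 and the genes called in both lines, which also turned over with each line fitted with its own batch. Total counts of genes called stayed within 1.5 times of the value reported with RLE or upper-quartile scaling, DESeq2, other filters and the 2 added fits. A fold threshold of 2 calls fewer genes by its construction: 8014 for DM6-DM7, 3670 for DM1-DM2d adr1s, 2339 for DM6-DM7 adr1s, 3362 for the DM6-DM7 effect minus its effect in adr1s, 7097 for the DM1-DM2d effect minus the DM6-DM7 effect, 634 between the lines in adr1s, 5320 and 2659 for Col-0 adr1s against Col-0 12 and 14 DAS, 5796 between the wild types, and 5963 in place of 11741 genes called in both lines. An adjusted p of 0.01 likewise gave 4799 for DM6-DM7 adr1s, 4177 for the DM6-DM7 difference of effects, 775 between the lines in adr1s and 5838 for Col-0 adr1s against Col-0 14 DAS. With no fold threshold 6508 genes of the DM6-DM7 response were called the same way in adr1s, in place of 3997.

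With only the libraries of the contrast in the fit, 3469 genes differed between the lines in adr1s, 5337 between Col-0 adr1s and Col-0 14 DAS and 6579 between the wild types; the cause was not tested. The replicate numbers did not pair samples: none of 14 pairs with the same number across groups had a residual correlation over 0.1 (-0.033 to 0.05). As a block they gave 5697 genes for Col-0 adr1s against Col-0 14 DAS, and 16224, 14652, 9582, 6930, 12949, 6767, 10747 and 1684 for the other within-batch and difference contrasts in the order of the report's design, from DM1-DM2d to the lines in adr1s. With an estimated correlation 1 list and contrast pair passed in place of 127.

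Leaving out each replicate gave 15329 to 16394 genes for DM1-DM2d, 13874 to 15016 for DM6-DM7, 8447 to 9066 for DM1-DM2d adr1s, 5392 to 6487 for DM6-DM7 adr1s, 12233 to 13145 and 5771 to 7752 for the differences from adr1s, 9696 to 12337 for the difference between lines, 994 to 1705 between the lines in adr1s, 8630 to 9938, 7074 to 9392 and 9645 to 12589 for the Col-0 contrasts, and 5043 to 5212 (DM1-DM2d) and 3191 to 3661 (DM6-DM7) genes of the response called in adr1s. A lone Col-0 12 DAS library was assumed to vary like the other groups. Why the count between the lines in adr1s fell so far was not tested.

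Of 256 named gene and contrast pairs 252 kept their side of the threshold under all alternatives run. CHS and COR47 in DM6-DM7 adr1s, ADR1 in the DM1-DM2d difference of effects and ADR1-L1 in that of DM6-DM7 passed it under some. Pairs whose calls held were preferred for naming, so this is no estimate for all genes, and 1 pair gave no value in the fit of its own libraries. Of 224 list and contrast pairs 222 were called alike with RLE scaling and 2 lost their call; with the block 209 were alike, 3 lost and 12 gained a call, and with fry 179, 6 and 39. In simulated data 46% to 59% of 2-fold changes were recovered; depth was not varied there.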

Other observations

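IPS1, a long non-coding RNA gene of phosphate starvation, had the difference of -13.27 ± 1.42 between the DM1-DM2d and DM6-DM7 effects. Without DM1-DM2d replicate 3 it was -14.2.

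Most mitochondrial genes were not called in any of the 4 comparisons of a line with its Col-0 group, and no test of them as a set was run. Of 104 mitochondrial genes 20 were higher and 1 lower in DM1-DM2d (median 0.47), and 32 higher and 3 lower in DM6-DM7 (median 0.92). In DM1-DM2d adr1s 18 were higher and none lower (median 0.73), and in DM6-DM7 adr1s 2 were higher (median 0.27). Their share of counts was 0.91 ± 0.031% in DM1-DM2d and 0.5 ± 0.0071% in Col-0 12 DAS, and at most 0.066% on average in the other groups.

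Genes of ribosomal RNA held 0.0062% of counts in DM1-DM2d and 0.0025% in Col-0 12 DAS on average, and between 0.26% and 0.39% in the other 5 groups, so the libraries of label batch 1 stood apart in all of these shares. On the first axis of a multidimensional scaling, which held 44.7% of the variance, the DM1-DM2d libraries lay at -5.96 to -5.83 and the Col-0 adr1s libraries at 3.26 to 3.57.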
